A study of Mus musculus with 4 samples.

How the data were processed

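RNA abundance was measured in Neuro-2A cells, a mouse neuroblastoma line, by digital gene expression (DGE), in which a short sequence tag next to a DpnII site of each polyadenylated transcript is sequenced and counted. Per the labels' protocols, cells were transfected by lipofection with a pRK5 plasmid carrying either Zac1 or the bacterial chloramphenicol acetyltransferase (CAT) gene as a negative control. Total RNA was taken 16 h later, and 2 µg of it went into each library, with 15 cycles of PCR. Each group held 2 libraries from separate transfections. Samples were assigned to groups by their titles, and libraries are named here by their group and the number in the title, 9 or 12.

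The deposited values were 1 table of 4 columns, with a gene symbol and a gene ID in each line. They were a normalized signal, not raw counts, since most were not whole numbers. Per the name of the deposited table they were pseudocounts after TMM normalization, and per the submitters' processing notes the tool was edgeR and the genome build mm9. The mapping of tags, their assignment to genes and the edgeR version are not given in the sources used here, so values of near-identical gene copies and of overlapping genes are uncertain. Genomic coordinates are not given, because the mouse annotation used here is of another build. Tags of the plasmid insert and of the chromosomal Plagl1 gene were not told apart.

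A pseudocount of this kind is a count moved to a common library size through the quantiles of a negative binomial distribution. That formula was inverted with 1 relative size per library and a common dispersion of 0.0364, both found from the values. Whole counts were recovered that returned 100% of the deposited signal values in all 4 columns, within an absolute tolerance of 1e-06. The inversion was tested on simulated data, where it recovered 100% of 51444 counts. Recovered totals were 11578920 for CAT replicate 9, 13840674 for CAT replicate 12, 12442532 for Zac1 replicate 9 and 12812457 for Zac1 replicate 12. The smallest total of a listed gene over the 4 libraries was 10 counts, so the table holds only genes with at least that many, and these totals cover listed genes only.

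The table had 12866 lines. In 5 of them no gene ID was given, and these were left out of the tests. They held 0% of the recovered counts of both CAT libraries, 0.00897% of those of Zac1 replicate 9 and 0.00438% of those of Zac1 replicate 12. A gene was tested if its mean over the 4 libraries was at least 10, which left 11433 genes and excluded 1428. Tests were run in R 4.3.3 with limma 3.58.1 on log2(value + 1), with a trend of the variance on abundance and no replicate term. They were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fold changes are on the log2(value + 1) scale, which understates changes of low genes. The p-values rest on the spread between the 2 transfections of each group. Most weight lies on the spread typical of genes of like abundance (prior degrees of freedom 14.1), not on that of the gene itself. A gene whose replicates differ widely can therefore pass.

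Of genes with 0 recovered counts in both CAT libraries, the fold is given as a lower bound against a floor of 3 counts per CAT library. Of genes with 1 to 3 counts in the CAT libraries together, the ratio of counts scaled to library size is given with an exact 95% interval. Bounds and intervals cover counting error only, since PCR copies of tags are not independent molecules. On data simulated from the means and library sizes of these libraries, for the comparison of Zac1 with CAT over 11389 genes, limma recovered 48% of 2-fold rises, 96% of 4-fold rises, 46% of 2-fold falls and 84% of 4-fold falls. It made 16 calls among 11189 unchanged genes. Its true calls were 24 rises of 2-fold, 48 rises of 4-fold, 23 falls of 2-fold and 42 falls of 4-fold. Each kind had 50 changed genes tested. False calls were thus a larger share of all calls in these simulated data than the adjusted p threshold is meant to allow.

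Before the data were examined, 21 gene lists were fixed from textbook knowledge, along with the test and the rule for naming genes. The lists covered core extracellular matrix, matrix-modifying enzymes, integrins and adhesion receptors, imprinted genes, reported Zac1 and PLAG-family targets, S and G2/M phase genes, p53 targets, neuronal genes, TGF-beta, BMP and WNT signalling, growth factor signalling, the unfolded protein response, heat shock and immediate early genes, the interferon response, sterol synthesis, glycolysis and hypoxia, ribosomal proteins, contractile genes, and markers of fibroblasts, endothelium, macrophages and glia. The 18 lists with at least 5 tested members were tested with limma camera at its preset correlation of 0.01, with adjustment over those lists. Camera with an estimated correlation was run beside it, and so was fry, which tests whether the members of a list move on balance one way and does not compare them with other genes.

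The naming rule took Plagl1, the 12 genes with the largest log2 fold change in each direction among those that passed with the same sign in both same-numbered pairs and had a mean of at least 20, up to 4 members of each list with the smallest p, and 12 imprinted genes tied to Plagl1. Where fewer than 12 genes passed in a direction, those with the smallest unadjusted p were taken as values only. List members are named in the text where they passed over all genes or over the list alone, or where a list had fewer than 5 tested members. Other genes are said to have been chosen after their values were seen. The values of some genes that the rule takes are not reported here, while counts over all genes and over lists include them.

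Alternatives covered the replicate number as a block, the pseudocount, the filter on low values, the scaling of the libraries, the variance trend and leaving out each library. Added after seeing the data were a loess correction of each library for transcript GC content, the lists without Plagl1, and tests on the recovered counts with edgeR 4.0.16 (quasi-likelihood, and exact with a common dispersion) and DESeq2 1.42.0. The edgeR quasi-likelihood test on the recovered counts called 150 genes. GC content was taken from the longest annotated transcript of each gene and was found for 99.4% of the genes tested.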

Results

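Transcript abundance was compared between Neuro-2A cells transfected with Zac1 and cells transfected with the CAT control, with 2 libraries per group, to find genes whose expression changes after Zac1 overexpression. Zac1 is the zinc-finger transcription factor encoded by Plagl1, an imprinted gene. Recovered tag totals ranged from 11578920 to 13840674 per library. The 20 most abundant genes took between 11.3% and 12.6% of the counts of a library. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 13.6 between the CAT libraries and 39.1 between the Zac1 libraries. Zac1 replicate 9 stood apart from the other 3 libraries, at 33.2 against CAT replicate 9 and 40.0 against CAT replicate 12, while Zac1 replicate 12 gave 13.4 and 12.8.

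Plagl1 (gene ID 22634) was at 0 in both CAT libraries and rose to a normalised count of 2436 ± 1359 (SD, n = 2) in the Zac1 libraries, 3397 in replicate 9 and 1475 in replicate 12. From the recovered counts it was at least 793-fold higher, and at least 480-fold without Zac1 replicate 9. Its log2 fold change was 11.13 ± 0.42 (SE), the largest of all genes tested (limma, Benjamini-Hochberg adjusted p = 1.15e-10). The value holds tags of the transfected plasmid as far as the authors' counting assigned them to the gene.

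After Zac1 transfection 110 of 11433 genes rose and 0 fell (limma, Benjamini-Hochberg adjusted p under 0.05). Rises were large: the median log2 fold change of these genes was 2.63, also with genes absent from the CAT libraries set at their lower bound, and 72 genes were over 4-fold higher. All 110 were higher in each Zac1 library than in the CAT library of the same number, which their selection from these same libraries favours. Many were nearly silent in control cells, with a mean normalised count under 10 in the CAT libraries for 46 of them and 0 counts in both for 8. At an unadjusted p under 0.05, limma gave 598 higher and 110 lower genes, and 443 and 434 after a correction of each library for GC content, which re-centres genes at each GC level. On the recovered counts, edgeR's quasi-likelihood test and DESeq2 also called 0 falls, and edgeR's exact test with a common dispersion called 4. The median GC content of the transcripts of the 110 genes was 58.3%, against 50% for the other genes tested, and 103 of them were higher in Zac1 replicate 9 than in replicate 12. The median log2 fold change of the 110 genes, which were selected with both Zac1 libraries, was 2.31 without Zac1 replicate 9 and 2.88 without Zac1 replicate 12. Without Zac1 replicate 9, or without Zac1 replicate 12, only Plagl1 passed, without CAT replicate 9 limma called 115 rises and 5 falls, and the correction for GC content left 50 rises and 0 falls.

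**Figure D1:**
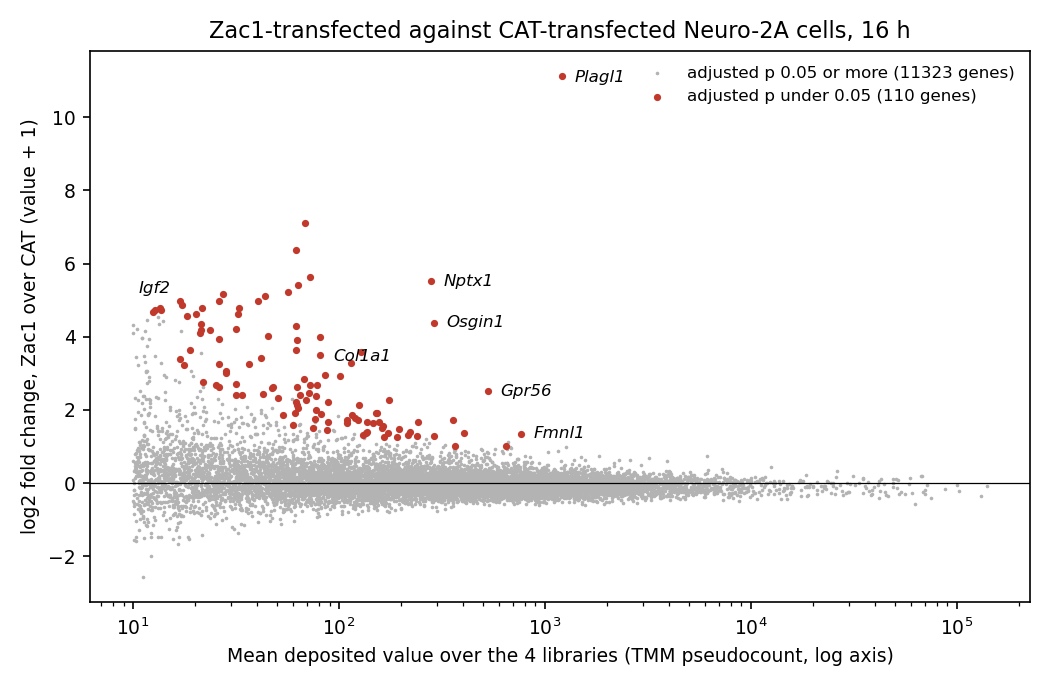
Log2 fold change, Zac1 over CAT (y axis), against the mean normalised count over the 4 libraries on a log axis (x axis), with 1 point per gene tested. The 110 genes that passed in limma are in red, all above 0, with Plagl1 highest at 11.13, and the genes labelled by symbol were picked to mark points of the plot.

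Below Plagl1, the genes with large rises were of several kinds. Kcnn4 (gene ID 16534), a calcium-activated potassium channel, rose from a normalised count of 1.99 ± 1.19 to 142 ± 28.7 (SD, n = 2; log2 fold change 5.62 ± 0.54 SE, limma adjusted p = 3.34e-05). Nptx1 (gene ID 18164), a secreted neuronal pentraxin, had the highest level of this group after Plagl1 and rose from 12.1 ± 9.26 to 546 ± 257 (5.51 ± 0.45, limma adjusted p = 5.67e-06). The septin gene Sept4 (gene ID 18952; 5.42 ± 0.56), the actin regulator Eps8l2 (gene ID 98845; 5.23 ± 0.79) and the WNT ligand Wnt10a (gene ID 22409; 5.11 ± 0.74) also rose. 5 further genes rose from 3 or fewer counts in the CAT libraries. The ratio of counts scaled to library size was 244 (95% interval 43.4 to 9670) for Tnni2 (gene ID 21953), fast skeletal troponin I, and 107 (18.8 to 4260) for Cnn1 (gene ID 12797), smooth muscle calponin. It was 102 (17.9 to 4070) for Gm98 (gene ID 225908), 63.6 (17.3 to 531) for the sphingosine-1-phosphate receptor gene S1pr4 (gene ID 13611), and 52.4 (17.6 to 257) for Adam11 (gene ID 11488). The ratio without Zac1 replicate 9 was 157 for Tnni2, 68 for Cnn1, 50.6 for Gm98 and 30.1 for S1pr4, and without Zac1 replicate 12 it was 96.5 for S1pr4. Without CAT replicate 9 it was 132 for Tnni2 and 85.1 for Adam11, without CAT replicate 12 it was 49 for Cnn1 and 46.8 for Gm98, and where the only CAT count was left out no ratio was formed. Of these genes none passed without Zac1 replicate 9 or without Zac1 replicate 12, where Plagl1 was the 1 call left. Eps8l2 also did not pass in limma without a trend (adjusted p = 0.0823) or in DESeq2 (0.368), with a range of 2.99e-22 to 0.818 over all alternatives.

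No gene passed as lower in limma, where the smallest adjusted p was 0.225, and the 12 genes with the smallest unadjusted p are given as values. Nudcd1 (gene ID 67429), the most abundant of them, had a normalised count of 1069 ± 6.29 (SD, n = 2) in the CAT libraries and 723 ± 65.3 in the Zac1 libraries. For Rbm15 (gene ID 229700), which encodes an RNA-binding protein, these values were 377 ± 7.15 and 223 ± 7.58. The log2 fold changes were -0.75 for Rbm15, -0.94 for BC005561, -0.80 for Jakmip2, -1.04 for F2rl2, -0.86 for 9430016H08Rik and -0.84 for 1110059E24Rik. They were -0.74 for the deubiquitinase gene Usp16, -0.75 for 2010107H07Rik, -1.15 for Slc25a43, -0.74 for Golim4, -1.26 for Pirt and -0.57 for Nudcd1, with -0.54 for 1110059E24Rik without Zac1 replicate 9 and -0.83 for Pirt without CAT replicate 12. Only edgeR's exact test with a common dispersion, on the recovered counts, called any of these 12 genes, with an adjusted p of 0.0224 for Pirt, which over all alternatives ranged up to 1.00.

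Among genes of the core extracellular matrix, 4 collagen genes and Tnxb rose. Of 56 members tested, 5 rose, 0 fell and 51 did not pass, and 6 rose when adjusted over the list alone. Col2a1, the main collagen of cartilage, rose from 20.2 ± 3.34 to 137 ± 26.7 (SD, n = 2; log2 fold change 2.69 ± 0.36 SE, limma adjusted p = 9.64e-04). Col1a1, a chain of the fibrillar collagen of bone and skin, rose from 11.9 ± 7.18 to 151 ± 102 (3.49 ± 0.51, limma adjusted p = 0.00215). Col9a2 rose with a log2 fold change of 3.63 ± 0.60 (limma adjusted p = 0.00518) and Col6a1 with 1.75 ± 0.35 (0.0202). Tnxb, which encodes a tenascin, is the remaining member that passed (4.11 ± 0.86, limma adjusted p = 0.0270), and was chosen after its values were seen. The list as a whole was higher, with 40 members higher and 16 lower, a median log2 fold change of 0.25, and a camera adjusted p of 6.83e-06. With an estimated correlation the adjusted p was 0.411. That estimate was -2.24e-04, below the preset 0.01, so correlation among the members is not what raised the adjusted p. The other alternatives of camera that kept all 4 libraries gave 7.86e-07 to 0.0222. The test fry, which asks whether the members move on balance one way and does not compare them with other genes, gave an adjusted p of 0.198. The median GC content of the members was 55.9%. After the correction for GC content Col6a1, at 1.51 ± 0.33 (adjusted p = 0.0950, range over alternatives 4.76e-06 to 0.818), and Tnxb, at 3.69 ± 0.87 (0.128, range 4.39e-10 to 0.841), did not pass. In limma without a trend Col1a1 (adjusted p = 0.0716, range over alternatives 1.23e-18 to 0.766), Col9a2 (0.0991, range 7.54e-17 to 0.818), Col6a1 (0.0740) and Tnxb (0.0902) did not pass, and no member passed without Zac1 replicate 9 or without Zac1 replicate 12. The series title names matrix genes, so the list is not independent evidence of their direction.

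Among matrix-modifying enzymes and inhibitors 1 of 40 members rose, and 2 rose when adjusted over the list alone. Sulf2, a sulfatase that acts on heparan sulfate, rose from 23.3 ± 1.54 to 104 ± 39.0 (SD, n = 2; log2 fold change 2.06 ± 0.38 SE, limma adjusted p = 0.0123). Tgm2, a transglutaminase, passed over the list alone (1.21 ± 0.30, limma adjusted p over all genes 0.0739). The median of the list was 0.05 (camera adjusted p = 0.221). Of 28 integrins and adhesion receptors 0 passed, with a median of 0.06 (camera adjusted p = 0.299). Sulf2 did not pass in limma without a trend (adjusted p = 0.0540, range over alternatives 1.54e-07 to 0.766), nor without Zac1 replicate 9 or 12. Tgm2 was at 0.76 without Zac1 replicate 9 (limma adjusted p over all genes 0.922) and at 1.46 without CAT replicate 12 (0.0191). It also passed over all genes under equal-total scaling (limma adjusted p = 0.0437), in edgeR's quasi-likelihood test (0.0349) and in DESeq2 (0.0225).

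Imprinted genes were tested because the series concerns the network of imprinted genes around Zac1. Of 41 members tested, 4 rose and 0 fell, namely Plagl1 itself, Igf2, Rian and Axl, and 7 rose when adjusted over the list alone. Igf2, the fetal growth factor gene, was at 0 in both CAT libraries and at 33.7 ± 21.1 (SD, n = 2) in the Zac1 libraries, at least 11-fold higher (log2 fold change 4.97 ± 0.98 SE, limma adjusted p = 0.0191), and at least 6.11-fold without Zac1 replicate 9. Rian, a noncoding RNA gene of the Dlk1 and Meg3 domain, rose from 32.0 ± 12 to 146 ± 5.09 (log2 fold change 2.20 ± 0.35 SE, limma adjusted p = 0.00345). Axl, a receptor tyrosine kinase gene, rose from 75.6 ± 21.9 to 199 ± 32.2 (1.40 ± 0.30, limma adjusted p = 0.0289). After the correction for GC content Igf2, at 4.76 ± 0.96 (adjusted p = 0.0577, range over alternatives 8.09e-13 to 0.766), and Axl, at 1.27 ± 0.28 (0.0974, range 1.03e-04 to 0.824), did not pass, and Axl did not pass without CAT replicate 9 (0.336) or in limma without a trend (0.145) either. Without Zac1 replicate 9 or 12 only Plagl1 passed.

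Of the 12 imprinted genes tied to Plagl1, 9 were tested, and of these only Igf2 passed over all genes. Cdkn1c, which encodes a cyclin-dependent kinase inhibitor, had 2 counts in the CAT libraries and 41 in the Zac1 libraries, a ratio of 19.8 (95% interval 5.13 to 169; 10.7 without Zac1 replicate 9), and did not pass in limma (adjusted p = 0.170), while limma without a trend gave 0.0438, edgeR's quasi-likelihood test on the recovered counts gave 0.0355 and the alternatives ranged from 3.85e-06 to 0.824. Meg3 was at 18.4 ± 10.004 and 58.3 ± 8.30 (SD, n = 2), a log2 fold change of 1.71 (limma adjusted p = 0.117), which depended on which CAT library was kept, at 2.26 without CAT replicate 12 (limma adjusted p = 0.0163) and 1.16 without CAT replicate 9 (adjusted p of 1). The values were 0.66 for Grb10, 0.37 for Dlk1, 0.18 for Gnas, 0.11 for Sgce, -0.03 for Mest and -0.56 for Peg3, and none of these passed. The value of Sgce was -0.04 without Zac1 replicate 9, and that of Mest 0.07 without CAT replicate 9. Mest was abundant and within replicate spread between the groups, at 15449 ± 1523 and 15135 ± 367. Dlk1 varied more within the groups than between them, at 647 ± 603 and 686 ± 394. Its spread went with the replicate number, at 220 in CAT replicate 9 and 408 in Zac1 replicate 9, against 1073 and 965 in the libraries numbered 12. Its log2 fold change was -0.77 without CAT replicate 9, -0.26 without Zac1 replicate 12 and 1.51 without CAT replicate 12. Fits without 1 library compare groups of unlike replicate numbers, so these values do not show an effect of Zac1 on Dlk1. H19 and Ndn were not analysed here, and Igf2r was below the minimum mean. The imprinted list had a median log2 fold change of 0.06, the same with absent genes at their bound, and a camera adjusted p of 0.0195. The adjusted p was 0.104 without Plagl1, 0.411 with an estimated correlation, 0.0831 without Zac1 replicate 9 and 0.226 without Zac1 replicate 12, and over all alternatives it ranged from 1.38e-12 to 0.411. The estimated correlation was -0.00349, again below the preset 0.01. With fry, which does not compare with other genes, the adjusted p was 0.294. As with matrix genes, the title names this group, which is not independent evidence of its direction.

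**Figure D2:**
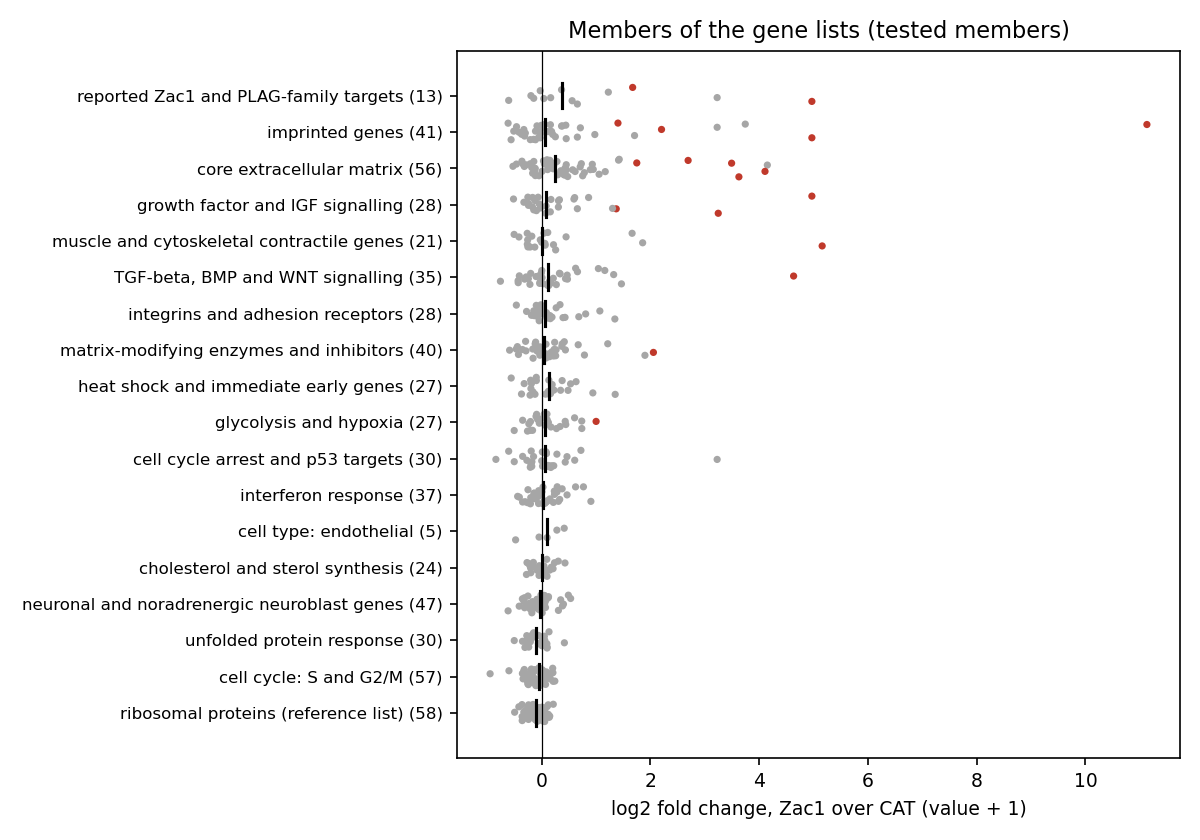
Log2 fold change, Zac1 over CAT (x axis), of the tested members of each gene list (y axis), with 1 point per gene, a vertical bar at the list median and the number of tested members in parentheses. Members that passed in limma over all genes are in red, and the core extracellular matrix list has the most, 5 of 56, followed by the imprinted list with 4 of 41.

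Of 13 reported targets of Zac1 and PLAG-family factors, 2 rose over all genes and 4 when adjusted over the list alone. Igf2, given above, was among the members that passed. Pparg, a nuclear receptor gene, passed over the list alone (1.23 ± 0.32, limma adjusted p over all genes 0.0945), as did Cdkn1c. Pparg depended on which CAT library was kept, at 1.66 without CAT replicate 9 (limma adjusted p = 0.0138) and 0.79 without CAT replicate 12 (adjusted p of 1). The list had 9 members higher and 4 lower, a median of 0.37 and a camera adjusted p of 0.0129. Its estimated correlation was -0.0281, below the preset 0.01. The camera adjusted p was 0.411 with an estimated correlation, 0.0674 without Zac1 replicate 9 and 0.206 without Zac1 replicate 12, within a range of 1.17e-04 to 0.411 over all alternatives, and fry, whose null is no change on balance of the members, gave 0.198. Without Zac1 replicate 9 or 12 no member passed over all genes.

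In the growth factor and IGF list 3 of 28 members rose over all genes and 4 over the list alone. These were Igf2 and the platelet-derived growth factor genes Pdgfb, from 6.03 ± 2.14 to 67.5 ± 29.7 (SD, n = 2; log2 fold change 3.25 ± 0.54 SE, limma adjusted p = 0.00553), and Pdgfa, from 215 ± 24.2 to 594 ± 299 (1.37 ± 0.30, limma adjusted p = 0.0343). Their receptor gene Pdgfrb passed over the list alone (1.30 ± 0.42, limma adjusted p over all genes 0.270). The estimated correlation of the list was -0.00936, below the preset 0.01. The list median was 0.08 and its camera adjusted p 0.0330, which was 0.411 with an estimated correlation, 0.0676 after the correction for GC content, 0.0831 without Zac1 replicate 9 and 0.206 without Zac1 replicate 12, the range over all alternatives being 0.00717 to 0.411, while fry, which does not compare with other genes, gave 0.198. Pdgfa did not pass after the GC correction, at 1.31 ± 0.30 (adjusted p = 0.108, range over alternatives 5.74e-06 to 0.818) or in limma without a trend (0.336) or without CAT replicate 9 (0.0953), and neither ligand gene passed without Zac1 replicate 9 or 12. Pdgfa was at 0.84 without Zac1 replicate 9, and Pdgfrb at 0.85 without CAT replicate 9.

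In the TGF-beta, BMP and WNT list 1 of 35 members rose over all genes and 3 over the list alone. Wnt6, a WNT ligand gene, had 2 counts in the CAT libraries and 131 in the Zac1 libraries, a ratio of 63.1 (95% interval 17.1 to 527; limma adjusted p = 0.00761), which was 22.4 without Zac1 replicate 9 and 103 without Zac1 replicate 12. Axin2, a target and inhibitor of WNT signalling, and Tgfb1 passed over the list alone, at 1.47 ± 0.35 and 1.04 ± 0.25 (limma adjusted p over all genes 0.0675 for both). As a whole the list had a median of 0.11 and did not pass (camera adjusted p = 0.115). It passed in camera without the filter on low values (0.0432) and after the correction for GC content (0.0478). It did not pass with an estimated correlation (0.565) or with fry, which does not compare with other genes (0.387). Wnt6 did not pass without Zac1 replicate 9 or 12, and Axin2 passed over all genes without CAT replicate 12 (limma adjusted p = 0.0379). Axin2 and Tgfb1 also passed over all genes under equal-total scaling (limma adjusted p = 0.0403 and 0.0400), in edgeR's quasi-likelihood test (0.0395 and 0.0325) and in DESeq2 (0.0363 and 0.0201), with ranges over alternatives of 1.02e-04 to 0.911 and 0.00258 to 0.818.

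Ribosomal protein genes were the 1 list that passed as lower. Of 58 members 43 were lower and 15 higher, with a median log2 fold change of -0.11, and 0 passed by themselves. The camera adjusted p was 0.0214. It was 0.565 with an estimated correlation, 0.633 without Zac1 replicate 9 and 0.159 without CAT replicate 12, and it ranged from 0.00399 to 0.633 over all alternatives. With fry, which does not compare with other genes, the adjusted p was 0.436.

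Lists of other cell functions did not pass the threshold with limma camera. S and G2/M phase genes had 0 of 57 members past the threshold and a median of -0.05 (adjusted p = 0.0916). That list passed as lower without the filter on low values (camera adjusted p = 0.0479), and gave 0.411 with an estimated correlation. The 30 p53 and arrest genes (median 0.07, adjusted p = 0.767), 47 neuronal and noradrenergic genes (-0.03, 0.430), 30 unfolded protein response genes (-0.10, 0.103) and 37 interferon response genes (0.03, 0.934) had 0 members past the threshold. Among 27 heat shock and immediate early genes, with a median of 0.13 (adjusted p = 0.353), Nr4a1 passed over the list alone (0.94 ± 0.22, limma adjusted p over all genes 0.0541). Nr4a1 passed over all genes under median-of-ratios and equal-total scaling (limma adjusted p = 0.0481 and 0.0292), in edgeR's quasi-likelihood test (0.0346) and in DESeq2 (0.00697), within a range of 0.00697 to 0.766 over all alternatives. In the glycolysis and hypoxia list 1 of 27 members rose, the neuronal enolase gene Eno2, from 435 ± 80.9 to 865 ± 76.4 (SD, n = 2; 1.00 ± 0.23, limma adjusted p = 0.0489), and the list median was 0.06 (camera adjusted p = 0.361). The direction of that list depended on the library left out. It was lower without CAT replicate 9 or Zac1 replicate 12, and higher without CAT replicate 12 or Zac1 replicate 9. With all 4 libraries its estimated correlation was 0.551, above the preset 0.01. Camera with that estimate gave an adjusted p of 0.864, and fry, which does not compare with other genes, gave 0.917. Eno2 did not pass after the correction for GC content, at 0.84 ± 0.21 (adjusted p = 0.186, range over alternatives 0.00288 to 1.00), in limma without a trend (0.254) or with a pseudocount of 0.5, nor when any of the 4 libraries was left out. Of 21 contractile genes Cnn1 passed over all genes and Actc1 over the list alone (1.66 ± 0.46, limma adjusted p over all genes 0.123, and 0.0460 without a trend), with a list median of 0 (camera adjusted p = 0.602). The 24 sterol synthesis genes had a median of 0.004 and a mean of 0.001 while camera gave the opposite direction (adjusted p = 0.934).

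Markers of cell types other than the line were mostly too low to test. Of the endothelial markers 5 were tested, with a median of 0.10 and 0 past the threshold (camera adjusted p = 0.751). The fibroblast list had 2 tested members, of which Col1a1 rose, as given for the matrix list, and S100a4 had a log2 fold change of 0.07 (limma adjusted p = 0.990), which was -0.19 without Zac1 replicate 12 and 0.33 without Zac1 replicate 9. The macrophage list had 1, Fcer1g, at 0.12 (0.989), and 0.01 to 0.23 with 1 library left out. The glial list had 1, Mbp, at 0.42 (0.932), which was 0.67 without CAT replicate 9 and 0.18 without CAT replicate 12.

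**Figure D3:**
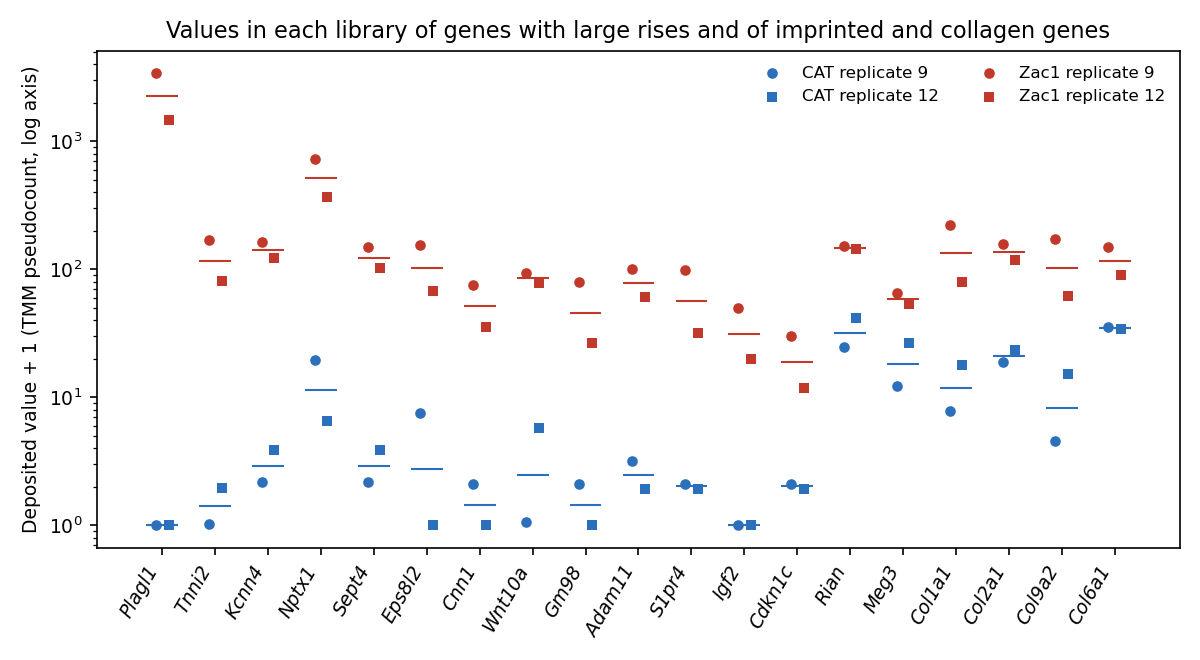
Normalised count plus 1 on a log axis (y axis) in each of the 4 libraries, for the genes named along the x axis, with circles for replicate 9, squares for replicate 12, blue for CAT, red for Zac1, and bars at the geometric mean of each group. For Plagl1 the CAT libraries sit at a count of 0 and the Zac1 libraries at 3397 and 1475.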

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

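The GC correction and the tests of genes that lead without Zac1 replicate 9, of Plagl1 in replicate 9, of genes abundant in CAT libraries and of other splits were chosen after the results they bear on were seen. In 5 lines of the deposited table no gene ID was given; they enter no comparison, and each had 0 recovered counts in both CAT libraries and counts in the Zac1 libraries, which is why they are listed. The line ZpA+2_S had 1434 counts in the Zac1 libraries, 939 in replicate 9 and 495 in replicate 12. The line Z13_A had 184 counts there, 132 and 52. For Z9_A the Zac1 libraries held 26 counts, 23 and 3. For ZpA-9_S they held 22 counts, 11 in each. For Z14_A they held 11 counts, all in replicate 9.

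Genes that rose were GC-rich: 55 of the 110 lay in the highest of 10 equal bins of tested genes by transcript GC content and 1 in the lowest, and across genes, which are not independent replicates, the difference from the CAT mean went with GC content more in Zac1 replicate 9 (Spearman's rho 0.321) than in Zac1 replicate 12 (0.126). A GC tilt of the library of Zac1 replicate 9 is argued against as the whole cause, because in the comparison made without that library the 110 higher genes with the smallest p, 79 of them among the genes called, had a median GC content of 57.7%, above the 52.6% that bounded the central 95% of 10000 lists matched on mean value. The GC correction ended 60 of the 110 calls, whose median log2 fold change went from 1.89 to 1.53, with a median SE of 0.38 before and 0.37 after and a median unadjusted p of 1.9e-04 before and 7.4e-04 after, while the prior degrees of freedom of the limma fit went from 14.1 to 10.8; which of these ended the calls was not tested. A candidate explanation on the biological side is that GC-rich genes rise in their own right. The 50 genes called after the correction had a median GC content of 57.5%. This was above 53.2%, the upper end of the range that held the central 95% of 10000 lists matched on mean value. All 50 were among the 110 genes called before it, whose median was 58.3%, so the value does not decide the question. A GC effect shared by both Zac1 libraries and not removed by this correction stays open and was not tested.

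Rises were larger in Zac1 replicate 9 than in Zac1 replicate 12, with a median log2 difference between them of 0.68 over the 110 genes and -0.03 over the other genes tested. A tilt with transcript GC content is argued against as the whole cause. After the correction the median difference was 0.509, and 95 of the 110 genes were higher in replicate 9. The central 95% of 10000 lists matched on GC content and mean value ran from -0.03 to 0.24. GC content of the sequenced tags was not measured, so a tilt with tag GC content stays open. Plagl1 itself was higher in replicate 9, by 1.203 on the log2 scale, so more transfected Plagl1 may go with larger rises. With 1 library at each level, the amount of Plagl1 and any other difference between the 2 libraries, such as a wider spread of replicate 9 in genes called on the mean of both, cannot be told apart.

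The comparison gave 110 rises and 0 falls in limma, where 110 other genes were lower at an unadjusted p under 0.05, while edgeR's exact test with a common dispersion called 4 falls and limma without CAT replicate 9 called 5. Scaling between libraries stays open: falls were 0% of the calls under both other scalings, but the bound set on this was wrong, since these moved the median log2 fold change of all genes from -0.01 only to -0.01 and 0.05, which is too little or toward rises and could not have made falls. That limma missed falls which edgeR's quasi-likelihood test on the recovered counts finds is argued against, since falls were also 0% of the calls of that test. Both tests used the same 4 libraries, and in simulated data they recovered 46% and 52% of 2-fold falls. Falls that both tests miss therefore stay open. Among 8318 genes with a CAT mean of at least 100, which had room to fall, there were 13 rises and 0 falls. An exact two-sided sign test over these called genes, which are not independent, gave p = 2.44e-04. With 0 falls over all genes this subset could hold none, so the sign test cannot decide whether low abundance in control cells is the cause. The 13 rises show only that rises without falls were not confined to genes of low abundance, though most of the 110 rises lay below that level. The GC correction left 50 rises and 0 falls at the threshold. With the replicate number added as a block it gave 173 rises and 30 falls, but the labels do not say that the numbers pair libraries. At an unadjusted limma p under 0.05 the correction gave 443 higher and 434 lower genes, where there were 598 and 110 before. As it re-centres genes at each GC level, which moves counts toward balance by itself, a share of GC content in the imbalance stays open. Whether Zac1 mainly raised transcripts at 16 h is therefore open, as are falls near 2-fold, of which limma recovered 46% in simulated data.

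Of the 3 splits of the 4 libraries into 2 and 2, only the real split called as many as 110 genes (1 of 3). The highest of the others called 9, with both libraries numbered 12 against both numbered 9. A number of 3 splits is too small to give a share under 0.05.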

How the results depend on the processing

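The GC correction, the count tests and the lists without Plagl1 were chosen after seeing the data, and the other settings before. Plagl1 passed under every setting. The 110 rises all remained higher under every setting in which they were tested. They were selected as rises from these same libraries, so the kept direction is no separate evidence. Their number stayed within 1.5 times under both pseudocounts (107 and 111), no filter (124), median-of-ratios scaling (115), equal-total scaling (138), no trend (79, of which 49 were shared), edgeR's quasi-likelihood test (150) and DESeq2 (143). It was 67 at a mean of at least 50, where fewer genes were tested, 50 after the GC correction, and 345 with edgeR's exact test with a common dispersion, of which 4 were falls (Fam171b, Pirt, Pcdhb15 and Lysmd3). Leaving out 1 library gave 1 to 154 calls: 1 without Zac1 replicate 9, 1 without Zac1 replicate 12, 154 without CAT replicate 12, and 120 with 5 falls without CAT replicate 9. In those fits the lone library was assumed to vary like the other group. With the replicate number as a block, 279 genes passed, 110 of them shared, and with the GC correction and the block 203, of which 30 were falls. The labels do not say that the numbers 9 and 12 pair libraries, and the deviations of same-numbered libraries correlated at 0.2 across genes, which with 2 pairs does not establish a pairing. The 5 gene lists that passed became 8 without a filter, 1 at a mean of at least 50, 2 to 7 with 1 library left out, 0 with an estimated correlation and 0 with fry. Directions reversed for results that had not passed. Mest was at 0.036 under equal-total scaling, at 0.011 after the GC correction with and without the block, and at -0.127 to 0.074 with 1 library left out. Gnas was at -0.111 after the GC correction with and without the block. With 1 library left out the ranges were -0.773 to 1.505 for Dlk1, -0.041 to 0.266 for Sgce and -0.193 to 0.329 for S100a4. The lists that follow each reversed under at least 1 of the settings given, with camera adjusted p-values unless fry is named, and the ranges with 1 library left out also hold settings that did not reverse. The interferon list gave 0.954 without a filter, 0.95 at a mean of at least 50 and 0.65 to 0.943 with 1 library left out. Sterol synthesis gave 0.893 at that mean, 0.989 with fry and 0.0523 to 0.328 with 1 library left out. Contractile genes gave 0.437, 0.987 after the GC correction and 0.0724 to 0.943. For p53 targets it was 0.708 after the GC correction, 0.581 with the block added and 0.616 to 0.966, and for endothelial markers 0.938, 0.855 and 0.588 to 0.966. Glycolysis and hypoxia genes gave 2.44e-05 to 0.328 with 1 library left out. Of the other values of single genes and lists, each under 1 setting, 1216 kept their direction and side of the threshold, 140 lost a call and 52 gained one. Where no cause is named, the cause was not tested. Depth limits the 46 called genes with a mean under 10 in the CAT libraries, and at this size of study limma found 48% of simulated 2-fold rises.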

Other observations

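The genes here were chosen after their values were seen and stand for no common theme. Osgin1, an oxidative stress-induced growth inhibitor, had the smallest adjusted p after Plagl1 and rose from 26.4 ± 9.55 to 552 ± 72.8 (SD, n = 2; log2 fold change 4.38 ± 0.30 SE, limma adjusted p = 7.17e-07), with similar values in both Zac1 libraries. Gpr56, an adhesion G protein-coupled receptor, was among the more abundant genes that rose, from 158 ± 49.5 to 904 ± 276 (2.51 ± 0.28, limma adjusted p = 1.38e-04). Wnt10b, a WNT ligand gene, rose from 4.13 ± 1.92 to 86.0 ± 44.8 (4.03 ± 0.57, limma adjusted p = 0.00169). Kremen2 and Notum, whose products dampen WNT signalling, rose with log2 fold changes of 2.96 ± 0.40 and 2.70 ± 0.51 (limma adjusted p = 0.00104 and 0.0143). Notch3, a Notch receptor gene, rose with 3.07 ± 0.56, Hes7 with 2.69 ± 0.41 and Dtx1 with 1.29 ± 0.27 (limma adjusted p = 0.0106, 0.00308 and 0.0270).

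Other genes chosen in the same way rose from 0 to 3 counts in the CAT libraries, or, for Lif, from a low level. Pnmt, which makes adrenaline from noradrenaline, had 0 counts in both CAT libraries and 55 in the Zac1 libraries, at least 8.79-fold higher (limma adjusted p = 0.0270). Slc4a1, the anion exchanger of red cells, had 0 and 71 counts, at least 11.3-fold higher (limma adjusted p = 0.0302), with bounds of 4.5 without Zac1 replicate 9 and 18 without Zac1 replicate 12. Sfpi1, a transcription factor gene of blood cells, had 3 and 104 counts, a ratio of 33.4 (95% interval 11.1 to 165; limma adjusted p = 0.0302), which was 10.4 without Zac1 replicate 9 and 56.1 without Zac1 replicate 12. Clcf1, a cytokine gene, had 2 and 85 counts, a ratio of 41 (11 to 344; limma adjusted p = 0.0493), which was 13.6 without Zac1 replicate 9, 67.9 without Zac1 replicate 12 and 18.8 without CAT replicate 12, and the related cytokine gene Lif rose from 23.9 ± 0.68 to 98.2 ± 45.3 (SD, n = 2; 1.91 ± 0.40, limma adjusted p = 0.0270). Without Zac1 replicate 9 or 12 none of the genes named here passed, and after the GC correction Osgin1, Gpr56, Wnt10b, Kremen2 and Hes7 passed and the others did not. The log2 fold changes of those others before and after that correction were 2.70 ± 0.51 and 2.32 ± 0.51 (SE) for Notum, 3.07 ± 0.56 and 2.68 ± 0.54 for Notch3, 1.29 ± 0.27 and 0.82 ± 0.25 for Dtx1, 4.78 ± 0.99 and 4.37 ± 0.97 for Pnmt, 4.85 and 4.68 for Slc4a1 (SE 1.03 before), 3.94 ± 0.84 and 3.59 ± 0.83 for Sfpi1, 4.18 ± 0.96 and 3.96 ± 0.96 for Clcf1, and 1.91 ± 0.40 and 1.83 ± 0.39 for Lif. In limma without a trend Clcf1 (adjusted p = 0.118), Lif (0.0915), Dtx1 (0.220) and Sfpi1 (0.0902) did not pass, Clcf1 did not pass with either other pseudocount (0.0605 and 0.0556), and Dtx1 did not pass without CAT replicate 12 (0.290). Over all alternatives the adjusted p ranged up to 0.880 for Clcf1 and up to 0.818 for the other 3.

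A hypothesis written before its test was that families of genes sharing a symbol stem rise together. Over 118 stems with at least 10 tested members, 0 had more called members than 10000 draws matched on mean value and GC content gave, at a permutation p adjusted over the stems. The stem with the smallest p was Gpr, with 4 of 32 members called (Gpr124, Gpr153, Gpr4 and Gpr56) against 0.66 expected (permutation p = 0.003, adjusted 0.354). Collagen genes with the stem Col had 4 of 20 called against 1.28 expected (permutation p = 0.0295, adjusted 1.00). The data thus gave no family that passed.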
